A study of Arabidopsis thaliana with 12 samples.

How the data were processed

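Messenger RNA levels were measured by RNA sequencing in 12 libraries from Arabidopsis thaliana seedlings, labelled as leaves of 14-day-old plants. The wild type was Col-0. The second genotype carried TaF5H1, a wheat gene for ferulate 5-hydroxylase under its own wheat promoter. Ferulate 5-hydroxylase is the cytochrome P450 that leads the monolignol pathway towards syringyl lignin and sinapate. Seedlings of both genotypes were kept for 6 h in nutrient solution (untreated) or in 200 mM NaCl. Each of the 4 groups held 3 libraries, which the series description calls biological replicates.

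Per the labels, RNA was extracted with TRIzol and an RNeasy kit and made into libraries by standard Illumina protocols. The submitters' processing notes name bcl2fastq 2.17.1.14, cutadapt 1.9.1 and HISAT2 2.0.1, and the genome build TAIR10. The counting program, its treatment of reads that match several genes and its use of strand are not given in the sources used here. Reads of near-identical neighbouring or duplicated genes (light-harvesting and Rubisco small subunit genes, small heat shock proteins, a cluster of glutaredoxins, some glucosyltransferases and allene oxide cyclases) and of overlapping antisense genes may therefore be divided in an unknown way, and values of such genes are uncertain. The authors deposited raw counts (whole numbers, not normalized) for 34218 genes, and FPKM values. FPKM is a gene's count divided by exon length and library total, and a recalculation from these matched within 0.005. Structural RNA genes held at most 0.00629% of the library totals. Coordinates are as deposited, 1-based on TAIR10. Of the 32548 loci also found in the TAIR10.1 reference annotation, 32532 had the same start and end. Gene symbols came from the table, which names 14769 genes, or else from that annotation. The wheat transgene was not analysed here.

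A test on log2(FPKM + 1) had been planned. Because counts were found, the main test was edgeR's quasi-likelihood test on the deposited counts (edgeR 4.0.16, R 4.3.3), and the planned test became an alternative. All 12 libraries entered one model with a mean per group, so that the groups shared an estimate of the spread. Library sizes were scaled by TMM factors. The 17038 genes with a mean FPKM of at least 1 were tested, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. The 5 comparisons were salt against untreated in wild type and the line, the line against wild type without and under salt, and the interaction. The interaction is the log2 salt response of the line minus that of wild type. Throughout, "edgeR adjusted p" means this test and adjustment. Standard errors came from the log2 fold change and F statistic.

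The model, gene filter, comparisons, 26 gene lists, 5 marker lists and the rule for naming genes were set before the data were examined. All 463 list members had a row in the table, and 6 of them belonged to 2 or more lists. Lists were tested with camera (limma 3.58.1) on log2 counts scaled to the library size (prior count 2) and a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. With that setting 51 list calls were made, and 0 of them held when the correlation was estimated from the data. The second p is therefore printed beside each list. The phrase "adjusted over the list alone" marks counts for which only the members of the list were adjusted together. Where all 3 libraries of a group had 0 counts, the fold is a lower bound against 3 counts over the whole group, and with 1 to 3 counts the ratio is given with its 95% binomial interval. Such bounds and intervals cover counting error only. List medians were recomputed with genes at their bounds, and only 1 of them moved.

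Genes were named by rule. In each comparison the rule took the 6 highest and 6 lowest log2 fold changes among called genes with a symbol, a mean FPKM of at least 5 in the higher group and no overlap between the 3 libraries of each group (overlap was not considered for the interaction). It then took the 3 called members of each list with the smallest adjusted p, or the 1 smallest where none was called. In every comparison it also named FAH1, CYP84A4, OMT1, SOS1, HKT1, NHX1, P5CS1, NCED3 and RD29B. HKT1 lay below the expression filter and was not tested. In the table's naming SOS1 is NHX7, P5CS1 is P5CSA and RD29B is LTI65. Plotted genes outside this rule in a given comparison were chosen after their values were seen.

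Gene Ontology process terms, as the deposited table annotates them, were tested for enrichment among genes called with at least 2-fold change, by a one-sided hypergeometric test over 310 terms of 20 to 500 genes, against the 13663 tested genes with a term, with Benjamini-Hochberg adjustment. This enrichment was added after the data were seen. The test treats genes as independent draws, so its p does not measure variation between libraries. It may be too small where the genes of a term move together.

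The main test was checked on simulated counts with the means and depths of these libraries and 200 of 17038 genes changed. Of genes changed 4-fold, it recovered 92.1% for salt in wild type, 85.5% for salt in the line, 82.4% and 82.3% for the line without and under salt, and 60.4% for the interaction. Of genes changed 2-fold, it recovered 50%, 54.4%, 41.9%, 27.9% and 3.17% in the same order. The false share of calls was 2.13%, 8.74%, 6.06%, 7.5% and 8.11%, so that in all but the first it lay above the share that the adjustment aims at. Each value came from a single simulated data set, in which 20 photosynthesis genes were also shifted 1.5-fold. Genes called in the data made up 53.8%, 64.8%, 13.9%, 34.6% and 5.88% of those tested, a larger share than was simulated. Because the adjusted threshold depends on that share, these recoveries do not carry over to the data. The passing mark of the simulated check had been 80% for 4-fold changes and was lowered to 50% after the interaction missed it.

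Alternatives set in advance were no filter or a filter of FPKM 5, median-of-ratios scaling, quantile normalization, log2(FPKM + 0.1), sample weights, the replicate number as a block, a fit of only the groups compared, a minimum fold of 2, an estimated correlation for the lists, and leaving out each library in turn. DESeq2 1.42.0, edgeR's own expression filter and scaling by library totals alone were added after the data were seen. Limma on log2(FPKM + 1), the planned test, became an alternative then. Tables were handled with the R package data.table (version 1.17.8) and with pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15, and plots were drawn with matplotlib 3.10.9.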

Results

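Leaves of 14-day-old seedlings of wild type and the TaF5H1 line were compared by RNA sequencing, without salt and after 6 h in 200 mM NaCl. The series title gives cell wall synthesis and salt tolerance as the subjects. Library totals were 18737315, 19416517 and 20560942 counts in untreated wild type and 20745198, 21143907 and 18678493 in salt-treated wild type. They were 20201508, 20322179 and 20016554 in the untreated line and 17173618, 21651124 and 18222947 in the salt-treated line. Below, FPKM values are means of the authors' deposited FPKM ± SD over the 3 libraries of a group, log2 fold changes (log2FC) carry their standard error, and n = 3 in every group unless stated. Gene positions are on TAIR10.

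In a principal component analysis of the 17038 genes tested, salt treatment separated along the first component (71.6% of the variance), on which untreated wild type lay at -114.6, -107.3 and -108.9 and salt-treated wild type at 55.1, 59.0 and 44.6. The untreated line lay to the salt side of untreated wild type, at -65.0, -64.4 and -75.0, and the salt-treated line lay beyond salt-treated wild type, at 91.1, 142.6 and 142.7. Replicate 1 of the salt-treated line stood apart from its fellows, with correlations of 0.931 and 0.935 with them over genes, against 0.989 between the other two. No pair of replicates was alike enough to be the same library (lowest chi-square per degree of freedom 6.53).

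**Figure D1:**
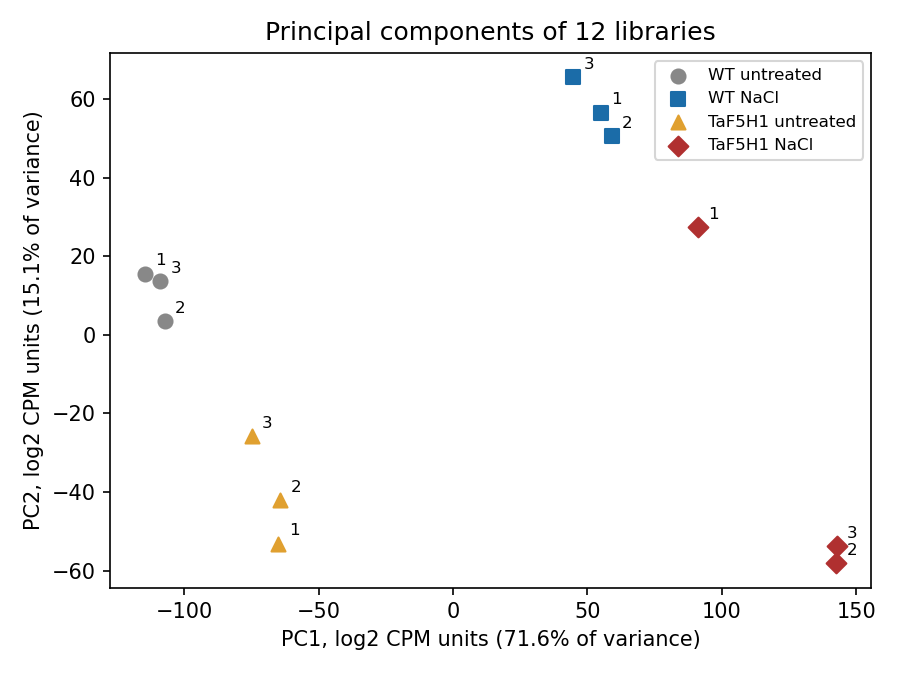
Principal component scores of the 12 libraries from log2 counts scaled to library size, with the first component (71.6% of the variance) on the horizontal axis and the second (15.1%) on the vertical axis; each point is a library, coloured by group and numbered by replicate. Replicate 1 of the salt-treated line (91.1 on the first component) lies between the salt-treated wild type and the other two libraries of its group.

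Salt treatment of wild type raised the genes of the abscisic acid (ABA) and dehydration response by more than any other list. All 18 measured members rose (18 also when adjusted over the list alone), with a median log2FC of 6.03 (camera adjusted p = 2e-15, and adjusted p = 0.12 with an estimated correlation). The cold- and ABA-inducible gene KIN1 (AT5G15960, chromosome 5, 5209717 to 5210826) went from 1.48 ± 0.729 to 2240 ± 59.2 FPKM (log2FC 10.75 ± 0.49, edgeR adjusted p = 2.8e-08). The dehydrin gene XERO2 (LTI30, AT3G50970, chromosome 3, 18940643 to 18941611) went from 2.12 ± 0.611 to 508 ± 30.3 (8.10 ± 0.27, edgeR adjusted p = 8.8e-09). LTI65 (RD29B, AT5G52300, chromosome 5, 21237021 to 21239531), a common reporter of ABA signalling, went from 0.45 ± 0.246 to 133 ± 9.05 (8.40 ± 0.56, edgeR adjusted p = 3.4e-07). NCED3 (AT3G14440, chromosome 3, 4831286 to 4834015), which encodes the rate-limiting dioxygenase of ABA synthesis, rose from 6.10 ± 2.58 to 72 ± 12 (3.77 ± 0.31, edgeR adjusted p = 1.6e-06).

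Several other parts of the ABA pathway moved with these genes in wild type. All 7 measured PP2C phosphatases, which restrain ABA signalling, rose (7 also when adjusted over the list alone, median 2.58, camera adjusted p = 4.9e-06, adjusted p = 0.12 with an estimated correlation). AIP1 (HAI2) rose by 4.09 ± 0.18 (edgeR adjusted p = 2.8e-08) and ABI1 by 2.58 ± 0.16 (edgeR adjusted p = 2.5e-07). Among the PYR/PYL receptors 1 rose and 2 of 7 fell, including PYL4, which fell by 2.99 ± 0.29 (edgeR adjusted p = 6.3e-06). Of the 9 genes of ABA synthesis and breakdown 6 rose and 1 fell (median 1.46, camera adjusted p = 0.015, adjusted p = 0.25 with an estimated correlation). That call ended with a filter of FPKM 5 (median 1.37, camera adjusted p = 0.055). Stress transcription factors rose in 19 of 26 cases and fell in 1 (20 and 1 adjusted over the list alone, median 1.46, camera adjusted p = 3.8e-06, adjusted p = 0.37 with an estimated correlation). The homeodomain gene ATHB-12 rose from 8.76 ± 0.42 to 165 ± 10.7 (4.43 ± 0.17, edgeR adjusted p = 1.4e-08), and NAC032 by 2.74 ± 0.16 (edgeR adjusted p = 1.2e-07).

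Ion transport and osmolyte genes responded gene by gene in wild type. NHX1 (AT5G27150, chromosome 5, 9553300 to 9557594), the vacuolar sodium/proton antiporter, rose from 59.4 ± 4.86 to 217 ± 9.06 (2.07 ± 0.16, edgeR adjusted p = 1.4e-06). The outward potassium channel gene GORK rose by 2.31 ± 0.30 (edgeR adjusted p = 5.6e-05), whereas NHX4 fell by 2.71 ± 0.33 (edgeR adjusted p = 3.7e-05). SOS1 (NHX7), the plasma membrane antiporter, was at 4.92 ± 0.231 and 4.98 ± 0.32 (0.22 ± 0.16, edgeR adjusted p = 0.28). Of 17 transport genes 6 rose and 6 fell. Proline synthesis genes rose, P5CSA by 1.48 ± 0.40 (edgeR adjusted p = 0.0081) and P5CSB by 2.04 ± 0.21 (edgeR adjusted p = 1.1e-05), as did the galactinol synthase gene GOLS1 by 5.90 ± 0.56 (edgeR adjusted p = 5.6e-06). In that list 6 of 13 rose and 3 fell.

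Phenylpropanoid genes also rose with salt in wild type. Of 19 monolignol genes 11 rose and 3 fell (12 and 3 adjusted over the list alone, median 0.65, camera adjusted p = 0.015, adjusted p = 0.25 with an estimated correlation). The call ended with a filter of FPKM 5 (median 0.50, camera adjusted p = 0.083). CAD5 (AT4G34230, chromosome 4, 16386631 to 16388940), a cinnamyl alcohol dehydrogenase of the last monolignol step, rose from 14.6 ± 2.55 to 473 ± 12.5 (5.22 ± 0.18, edgeR adjusted p = 1e-08). The methyltransferase gene OMT1 (AT5G54160, chromosome 5, 21981902 to 21984399) went from 29.9 ± 0.859 to 136 ± 5.19 (2.38 ± 0.15, edgeR adjusted p = 2.7e-07). FAH1 (CYP84A1, AT4G36220, chromosome 4, 17137313 to 17139777), the Arabidopsis ferulate 5-hydroxylase, was at 13.2 ± 0.569 and 8.86 ± 0.30 (-0.38 ± 0.27, edgeR adjusted p = 0.25). Its relative CYP84A4 was called at 1.29 ± 0.48 (edgeR adjusted p = 0.04). That call ended on leaving out any of 7 libraries (highest adjusted p 0.11, without replicate 1 of salt-treated wild type). So it did with library totals alone (1.09, edgeR adjusted p = 0.066) and limma on log2(FPKM + 0.1) (1.04, adjusted p = 0.066). Flavonoid and anthocyanin genes rose in 9 of 11 cases (median 1.81, camera adjusted p = 0.00068, adjusted p = 0.37 with an estimated correlation). The median was 3.18 without replicate 1 of untreated wild type. The anthocyanin regulator MYB90 (AT1G66390, chromosome 1, 24763941 to 24765541) had 0 counts in untreated wild type and 12.5 ± 1.85 FPKM under salt, at least 283-fold higher (edgeR adjusted p = 3.4e-06).

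Among genes that fell with salt in wild type were expansins and photosynthesis genes. Of 22 expansins and xyloglucan hydrolases, which loosen or remodel the primary wall, 11 fell and 3 rose in salt-treated wild type (median -0.90, camera adjusted p = 0.13). EXPA8 (AT2G40610, chromosome 2, 16948791 to 16950705) went from 27.5 ± 4.24 to 0.117 ± 0.146 FPKM (-7.68 ± 0.48, edgeR adjusted p = 1.2e-06). XTH25 (AT5G57550, chromosome 5, 23304782 to 23306440) went from 64.9 ± 11.3 to 4.56 ± 0.589 (-3.63 ± 0.44, edgeR adjusted p = 3.3e-05). The brassinosteroid synthesis gene CYP90B1 (DWF4) fell by 1.61 ± 0.17 (edgeR adjusted p = 1.3e-05). Light harvesting and Rubisco genes fell in 15 of 20 cases (median -1.45, camera adjusted p = 0.00068, adjusted p = 0.73 with an estimated correlation). LHCB4.2, for example, went from 388 ± 38.4 to 89.6 ± 9.06 (-1.91 ± 0.40, edgeR adjusted p = 0.0017). Of 14 secondary wall cellulose and xylan genes 4 rose, IRX7 (FRA8) by 3.67 ± 0.54 (edgeR adjusted p = 0.00016) and GATL1 by 0.85 ± 0.14 (edgeR adjusted p = 4e-04). The list was not called (median 1.04, camera adjusted p = 0.21), except with no filter on low expression (median 1.28, camera adjusted p = 0.042). Its mean level over untreated wild type was 0.27, 0.73 and 1.87 in the 3 salt-treated libraries, and without replicate 3 the median was 0.11 (camera adjusted p = 0.56).

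Jasmonate, heat shock and clock genes rose as well. In salt-treated wild type 15 of 24 jasmonate genes rose and 2 fell (17 and 2 adjusted over the list alone, median 0.79, camera adjusted p = 0.00068, adjusted p = 0.51 with an estimated correlation). Among them VSP2 rose from 104 ± 45.3 to 3080 ± 380 (5.08 ± 0.54, edgeR adjusted p = 1.3e-05). Heat shock genes rose in 10 of 12 cases and fell in 1 (median 4.32, camera adjusted p = 0.00068, adjusted p = 0.38 with an estimated correlation). The HSP70 gene MED37C rose by 4.38 ± 0.37 (edgeR adjusted p = 2.2e-06). Clock genes rose in 7 of 14 cases and fell in 1 (median 0.56, camera adjusted p = 0.015, adjusted p = 0.38 with an estimated correlation). With a filter of FPKM 5 the call ended (median 0.44, camera adjusted p = 0.21). The largest increases under the naming rule included the lipid transfer protein gene LTP4 (13.09 ± 2.19, edgeR adjusted p = 0.00039). SWEET15, a sugar exporter gene, was at 0 counts without salt and at least 446-fold higher with it (edgeR adjusted p = 7.7e-07). The largest decreases included the iron-responsive regulator BHLH100, at least 107-fold lower with salt (edgeR adjusted p = 0.00019), KCS12 (-6.20 ± 0.41, edgeR adjusted p = 3.2e-07) and FLA9 (-5.57 ± 0.47, edgeR adjusted p = 2.1e-06).

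In total edgeR called 9160 of 17038 genes for salt in wild type, 4616 up (50.4% of the calls) and 4544 down, of which 5084 changed at least 2-fold. Scaling by library totals alone shifted the median of all genes to -0.224 and the share of calls that were up to 36.8%, and limma on log2(FPKM + 1) gave 36.6%. Among genes called up with at least 2-fold change, 107 of the 267 annotated to water deprivation were found (37.8 expected, hypergeometric adjusted p = 1.9e-23), and 18 of 42 annotated to lignin synthesis (5.94 expected, adjusted p = 0.00014). Among genes called down by as much were 47 of 87 that the deposited annotation labels as receptor tyrosine kinase signalling (13.8 expected, hypergeometric adjusted p = 7.6e-14). Whether these genes encode tyrosine kinases was not checked.

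In the TaF5H1 line salt raised the same list of ABA and dehydration genes, with all 18 up (18 adjusted over the list alone, median 4.13, camera adjusted p = 5.4e-12, adjusted p = 0.18 with an estimated correlation). KIN1 went from 3.49 ± 0.94 to 1400 ± 521 FPKM (log2FC 8.92 ± 0.45, edgeR adjusted p = 5.1e-08). XERO2 went from 5.71 ± 1.31 to 824 ± 46.0 (7.43 ± 0.26, edgeR adjusted p = 9.1e-09) and LTI65 from 0.663 ± 0.0808 to 123 ± 80.3 (7.81 ± 0.54, edgeR adjusted p = 3.9e-07). NCED3 rose by 3.97 ± 0.31 (edgeR adjusted p = 9.1e-07) and NHX1 by 2.42 ± 0.17 (edgeR adjusted p = 3.9e-07). SOS1 (NHX7) was at 4.54 ± 1.16 and 4.83 ± 0.342 (0.35 ± 0.16, edgeR adjusted p = 0.079). All 7 PP2C phosphatases rose (7 adjusted over the list alone, median 3.04, camera adjusted p = 1e-05, adjusted p = 0.18 with an estimated correlation). P5CSA rose by 1.94 ± 0.41 (edgeR adjusted p = 0.0013), a value that was 1.23 without replicate 1 of the salt-treated line. Genes of ABA synthesis and breakdown rose in 5 of 9 cases (median 1.75, camera adjusted p = 0.036, adjusted p = 0.29 with an estimated correlation). This call ended without that same library (median 1.48, camera adjusted p = 0.089) and with a filter of FPKM 5 (median 1.65, camera adjusted p = 0.1).

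Phenylpropanoid genes rose in the line too, in 12 of 19 monolignol genes against 2 that fell (median 0.66, camera adjusted p = 0.012, adjusted p = 0.23 with an estimated correlation). CAD5 rose from 29.3 ± 0.435 to 618 ± 53.8 (4.66 ± 0.18, edgeR adjusted p = 1.6e-08) and OMT1 from 35.3 ± 5.09 to 183 ± 35.7 (2.63 ± 0.15, edgeR adjusted p = 1.1e-07). PAL3, a minor phenylalanine ammonia-lyase, fell from 8 ± 0.12 to 0.357 ± 0.197 (-4.23 ± 0.32, edgeR adjusted p = 7.4e-07). FAH1 was at 21.3 ± 3.26 and 25.9 ± 11.6 (0.53 ± 0.27, edgeR adjusted p = 0.1) and CYP84A4 at 1.64 ± 0.684 and 2.14 ± 1.76 (0.66, edgeR adjusted p = 0.26). UGT84A2 (AT3G21560, chromosome 3, 7595680 to 7597607), a sinapate glucosyltransferase, rose from 7.68 ± 0.878 to 27.3 ± 2.66 (2.09 ± 0.14, edgeR adjusted p = 3.5e-07). Flavonoid genes rose in 9 of 11 cases (median 2.1, camera adjusted p = 0.017, adjusted p = 0.75 with an estimated correlation). The lignin polymerization list differed in sign between its median (-0.52) and its mean (0.12), its direction turned with quantile normalization (0.27), and it was not called (camera adjusted p = 0.57).

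All 20 light harvesting and Rubisco genes fell with salt in the line (median -2.07, camera adjusted p = 9.3e-06, adjusted p = 0.78 with an estimated correlation). RBCS-1B fell from 741 ± 78.6 to 29.2 ± 29.8 (-4.37 ± 0.61, edgeR adjusted p = 7.3e-05). Expansins and xyloglucan hydrolases fell in 10 of 22 cases and rose in 6 (median -1.12, camera adjusted p = 0.47). EXPA8 had 3.20 ± 0.161 FPKM without salt and 0 counts with it, at least 67.5-fold lower (edgeR adjusted p = 1.4e-05). The expansin-like gene EXLA1 rose from 13.2 ± 2.32 to 176 ± 60.0 (3.98 ± 0.24, edgeR adjusted p = 1.6e-07). The primary wall cellulose genes fell in 7 of 11 cases and rose in 1. PME3, a pectin methylesterase gene, fell from 163 ± 16.0 to 14.1 ± 9.26 (-3.25 ± 0.37, edgeR adjusted p = 1.6e-05). Of 14 secondary wall genes 2 rose and 3 fell (2 and 1 adjusted over the list alone, median -0.95, camera adjusted p = 0.65).

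Stress transcription factors rose in 18 of 26 cases and fell in 2 in the line (median 1.51, camera adjusted p = 7e-05, adjusted p = 0.68 with an estimated correlation). Heat shock genes rose in 9 of 12 and fell in 2 (median 1.98, camera adjusted p = 0.029, adjusted p = 0.78 with an estimated correlation). The call ended without replicate 1 of the salt-treated line (median 1.93, camera adjusted p = 0.089). Of 18 salicylate and defence genes 8 rose, PBS3, a gene of salicylate synthesis, by 3.13 ± 0.40 (edgeR adjusted p = 4.2e-05). The mean level of this list over untreated wild type was 1.67, 3.46 and 3.35 in the 3 salt-treated libraries. Replicate 1 thus lay within the range of the untreated line (2.23, 1.81 and 1.25). In the jasmonate list 10 of 24 rose and 6 fell, with a median of -0.03 against a mean of 0.63, and the sign of the median turned with median-of-ratios scaling. The largest increases under the naming rule included DIR1, encoding a lipid transfer protein of systemic resistance, at 0 counts without salt and at least 260-fold higher with it (edgeR adjusted p = 3.1e-06). The ribonuclease gene RNS1 was among them (7.72 ± 0.36, edgeR adjusted p = 3.1e-08). The largest decreases included the homeodomain gene HAT3 (-7.34 ± 0.43, edgeR adjusted p = 1.1e-07) and PUP22 (-6.55 ± 0.28, edgeR adjusted p = 1.9e-08).

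For salt in the line edgeR called 11047 genes, 5346 up (48.4%) and 5701 down, with 6462 changed at least 2-fold. Scaling by library totals alone shifted the median of all genes to -0.31 and the share of calls that were up to 34.9%, and limma on log2(FPKM + 1) gave 34.3%. Across genes, which are not independent replicates, the salt responses of the genotypes correlated with r = 0.857 (Spearman 0.833) and a slope of 1.131 for the line on wild type. These comparisons share no libraries. Both genotypes had 3756 genes called up, where independent lists would share 1448, and 3668 called down, where they would share 1520, and 96 genes were called in opposite directions. Without a filter on low expression r was 0.626.

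Without salt the TaF5H1 line had lower expression of wall-loosening, cuticle and growth genes than wild type and higher expression of salicylate, anthocyanin and clock genes. Of 22 expansins and xyloglucan hydrolases 16 were lower and none was higher (19 and 0 adjusted over the list alone). The median log2FC was -2.02 (camera adjusted p = 4.1e-10, adjusted p = 0.13 with an estimated correlation). Higher members numbered 0 also at an unadjusted edgeR p under 0.05 (19 lower), by DESeq2 (15 lower) and by limma (16 lower). EXPA8 was at 3.20 ± 0.161 FPKM in the line and 27.5 ± 4.24 in wild type (-3.19 ± 0.33, edgeR adjusted p = 0.00066). XTH25 was at 8.18 ± 3.88 and 64.9 ± 11.3 (-3.08 ± 0.42, edgeR adjusted p = 0.0012) and EXLA1 at 13.2 ± 2.32 and 42.0 ± 3.81 (-1.76 ± 0.23, edgeR adjusted p = 0.00083). Growth genes of the auxin and brassinosteroid pathways were lower in 7 of 17 cases and higher in 1 (7 and 1 adjusted over the list alone, median -0.92, camera adjusted p = 0.00013, adjusted p = 0.36 with an estimated correlation). The auxin-responsive gene IAA19 (AT3G15540) was at 4.73 ± 0.911 against 17.5 ± 1.48 (-1.98 ± 0.16, edgeR adjusted p = 0.00012). CYP90B1 was at 3.59 ± 0.31 against 9.85 ± 0.506 (-1.54 ± 0.17, edgeR adjusted p = 0.00045).

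Cuticle genes followed in the untreated line, with 3 of 12 lower (6 adjusted over the list alone, median -0.89, camera adjusted p = 0.00027, adjusted p = 0.42 with an estimated correlation). CER1 (AT1G02205, chromosome 1, 418416 to 422579), required for alkane formation in leaf wax, was at 0.907 ± 0.376 against 21.5 ± 3.26 (-4.66 ± 0.57, edgeR adjusted p = 7e-04). The fatty acyl reductase gene FAR1 of the suberin list was at 0.303 ± 0.0451 against 2.00 ± 0.782 (-2.79 ± 0.40, edgeR adjusted p = 0.0014). Among pectin genes 2 of 10 were lower and 1 was higher (5 and 1 adjusted over the list alone, median -0.57, camera adjusted p = 0.016, adjusted p = 0.36 with an estimated correlation). PME41 was at 3.55 ± 0.708 against 20.1 ± 1.17 (-2.59 ± 0.25, edgeR adjusted p = 0.00024). The 11 primary wall cellulose genes had a median of -0.62 (camera adjusted p = 0.0011, adjusted p = 0.51 with an estimated correlation) although edgeR called 0 of them singly. At an unadjusted p under 0.05 edgeR put 7 of them lower, DESeq2 called 2 lower, and limma on log2(FPKM + 1) called 0.

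Of the lignin pathway, few genes differed in the untreated line. Among 19 monolignol genes 1 was higher and 2 were lower (2 and 2 adjusted over the list alone, median 0.06, camera adjusted p = 0.7). CAD5 was at 29.3 ± 0.435 against 14.6 ± 2.55 (0.92 ± 0.15, edgeR adjusted p = 0.0033). HST (HCT), a hydroxycinnamoyl transferase gene, was at 47.8 ± 2.23 against 72.3 ± 2.33 (-0.69 ± 0.12, edgeR adjusted p = 0.0036). FAH1 was at 21.3 ± 3.26 against 13.2 ± 0.569 (0.60 ± 0.27, edgeR adjusted p = 0.16), again without overlap. CYP84A4 was at 1.64 ± 0.684 against 2.02 ± 0.266 (-0.40, edgeR adjusted p = 0.63) and OMT1 at 35.3 ± 5.09 against 29.9 ± 0.859 (0.15, edgeR adjusted p = 0.53). Whether reads of the wheat transcript aligned to FAH1 was not tested. SNG1 (AT2G22990, chromosome 2, 9786087 to 9790335), which makes sinapoylmalate, was at 72.8 ± 6.29 against 138 ± 3.98 (-1.02 ± 0.12, edgeR adjusted p = 7e-04). The 14 secondary wall genes had a median of -0.05, which turned to 0.05 with library totals alone (camera adjusted p = 0.66). The median was -0.90 without replicate 2 of the untreated line (camera adjusted p = 0.14), a library with higher levels of 13 of the 14 genes than the mean of its fellows (median difference 1.36). Of these edgeR called 0, 1 had an unadjusted p under 0.05, DESeq2 called 1, and limma on log2(FPKM + 1) called 0.

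Salicylate and defence genes were higher in the untreated line in 10 of 18 cases (11 adjusted over the list alone, median 1.56, camera adjusted p = 7.7e-06, adjusted p = 0.39 with an estimated correlation). BGL2 (PR2, AT3G57260, chromosome 3, 21188397 to 21189967), a pathogenesis-related glucanase gene, was at 441 ± 171 against 53.2 ± 5.79 (2.96 ± 0.39, edgeR adjusted p = 0.00092). PR1 (AT2G14610, chromosome 2, 6241640 to 6242541), the usual marker of salicylate signalling, was at 96.0 ± 67.0 against 0.56 ± 0.219 (7.30 ± 1.43, edgeR adjusted p = 0.0071). Flavonoid genes were higher in 3 of 11 cases (4 adjusted over the list alone, median 1.42, camera adjusted p = 3.7e-05, adjusted p = 0.36 with an estimated correlation). That median was 2.97 without replicate 1 of untreated wild type and 0.79 without replicate 2 of the untreated line. MYB90 had 0 counts in untreated wild type and 9.76 ± 4.05 FPKM in the untreated line, at least 180-fold higher (edgeR adjusted p = 0.00024). Its paralog MYB75 was at 15.1 ± 1.58 against 1.64 ± 0.229 (3.10 ± 0.47, edgeR adjusted p = 0.0018). Clock genes were higher in 8 of 14 cases (11 adjusted over the list alone, median 0.83, camera adjusted p = 2.4e-06, adjusted p = 0.13 with an estimated correlation). Among them were GI (2.34 ± 0.27, edgeR adjusted p = 0.00056) and LNK1 (2.03 ± 0.24, edgeR adjusted p = 0.00064).

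Some ABA and stress genes were already higher in the line before salt. In the ABA and dehydration list these were 6 of 18 (11 adjusted over the list alone, median 0.64, camera adjusted p = 1.9e-05, adjusted p = 0.36 with an estimated correlation). Stress transcription factors were higher in 8 of 26 cases (8 adjusted over the list alone, median 0.59, camera adjusted p = 3.7e-05, adjusted p = 0.36 with an estimated correlation). The second median moved with single libraries, to 0.31 without replicate 1 of untreated wild type, 0.96 without replicate 2, 0.37 without replicate 3, and 0.32 without replicate 2 of the untreated line. XERO2 was higher by 1.34 ± 0.22 (edgeR adjusted p = 0.0032), ATHB-7 by 1.55 ± 0.21 (edgeR adjusted p = 0.001) and ATHB-12 by 1.06 ± 0.15 (edgeR adjusted p = 0.0014). LTI65 (0.47, edgeR adjusted p = 0.6), NHX1 (-0.22, edgeR adjusted p = 0.39), SOS1 (-0.20, edgeR adjusted p = 0.43) and P5CSA (-1.30 ± 0.40, edgeR adjusted p = 0.05) did not pass the test. Heat shock genes were higher in 5 of 12 cases (5 adjusted over the list alone, median 1.16, camera adjusted p = 3e-04, adjusted p = 0.36 with an estimated correlation). HSP90-1 was higher by 1.48 ± 0.26 (edgeR adjusted p = 0.004). Light harvesting and Rubisco genes had a median of -0.75 with 1 of 20 lower (0 adjusted over the list alone, 7 at an unadjusted p under 0.05 and 4 by DESeq2; camera adjusted p = 0.0011, adjusted p = 0.64 with an estimated correlation).

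By the naming rule the largest differences in the untreated line, besides that of MYB90, included the phosphoinositide kinase-like gene PI4KG3 (AT5G24240, chromosome 5, 8230916 to 8234150), at 25 ± 4.01 against 0.0967 ± 0.0473 (7.86 ± 0.82, edgeR adjusted p = 0.00031). Of the glutaredoxin genes, GRXS10 (chromosome 3, 7557297 to 7557969) was at 0.39 ± 0.165 against 14.0 ± 2.14 (-5.21 ± 0.34, edgeR adjusted p = 3.4e-05). GRXS7, which has near-identical neighbours, was at 0.55 ± 0.386 against 14.0 ± 2.32 (-4.74 ± 0.36, edgeR adjusted p = 0.00011). AGP17, an arabinogalactan protein gene, was at 1.31 ± 0.981 against 30.8 ± 0.854 (-4.64 ± 0.75, edgeR adjusted p = 0.0026). In all, edgeR called 2371 genes between the genotypes without salt, 1250 higher in the line (52.7%) and 1121 lower, with 1180 at least 2-fold. The higher share was 66.4% with library totals alone, 62% with limma on log2(FPKM + 1) and 63.3% with sample weights. The count was 1337 and 1160 without replicates 1 and 3 of untreated wild type, and 1211 and 1449 without replicates 1 and 2 of the untreated line. It was 5121 without replicate 1 of the salt-treated line, 3992 in a fit of these 6 libraries alone and 6065 with sample weights. Among genes higher by at least 2-fold, 11 of 43 annotated to systemic acquired resistance were found (1.57 expected, hypergeometric adjusted p = 2.1e-05), and among those lower, 16 of 88 annotated to unidimensional cell growth (2.96 expected, adjusted p = 4.9e-06).

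**Figure D2:**
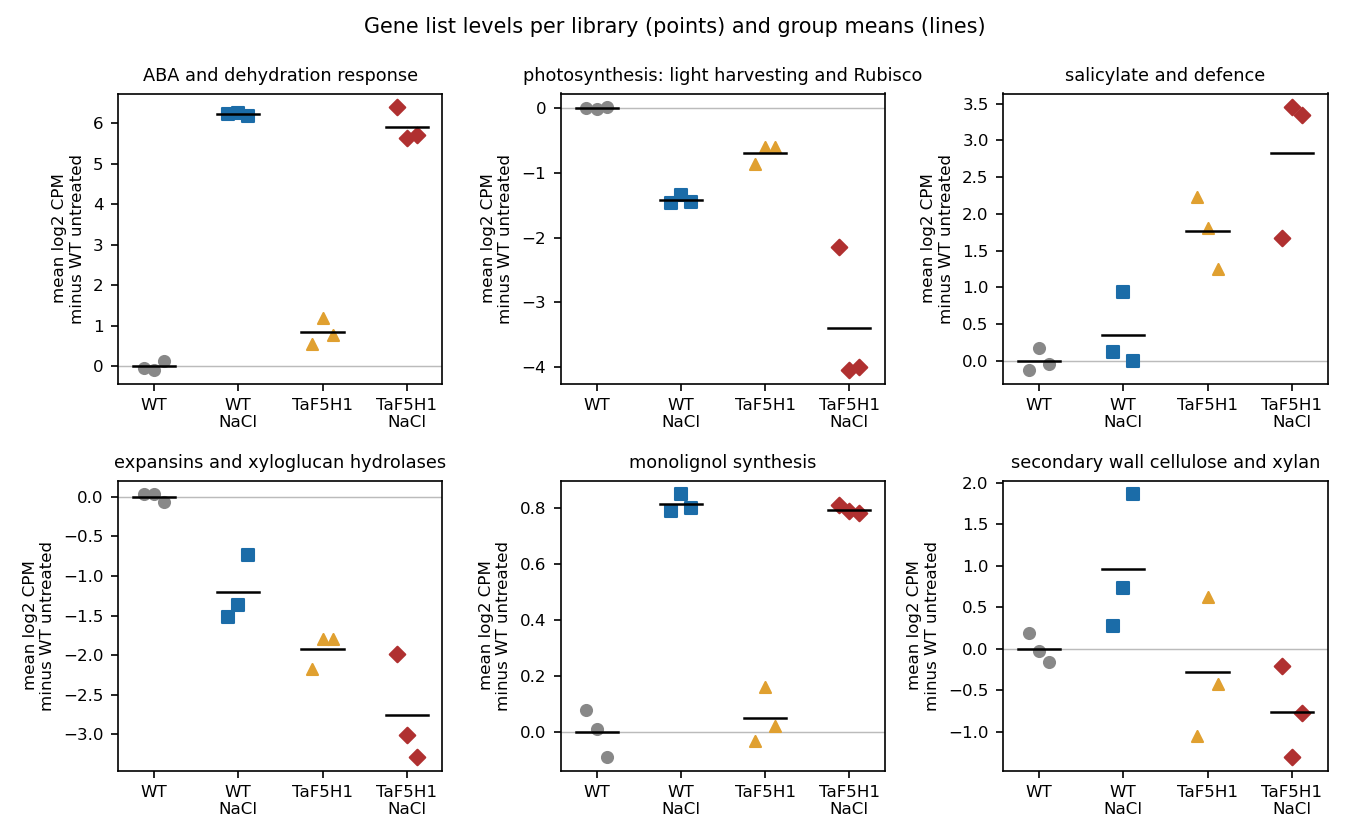
Mean log2 expression of 6 gene lists in each of the 12 libraries relative to the mean of untreated wild type (vertical axis, log2 units), by group on the horizontal axis; points are libraries and short lines are means of 3. Salt-treated libraries lie far above untreated ones for ABA and dehydration genes, and the salt-treated line lies above salt-treated wild type for salicylate and defence genes (median log2FC 2.53) and below it for photosynthesis genes (-1.55).

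Under salt the line differed from wild type most uniformly in defence and photosynthesis genes. All 18 salicylate and defence genes were higher (18 adjusted over the list alone, median log2FC 2.53, camera adjusted p = 7.2e-10, adjusted p = 0.52 with an estimated correlation). PBS3 was at 131 ± 50 FPKM against 22 ± 5.50 (2.54 ± 0.39, edgeR adjusted p = 0.0026). The defence regulator PAD4 was at 36.5 ± 13.4 against 11.1 ± 1.35 (1.67 ± 0.25, edgeR adjusted p = 0.0024). SARD1, a transcription factor for salicylate synthesis, was at 58.9 ± 31.5 against 10.2 ± 4.09 (2.47 ± 0.41, edgeR adjusted p = 0.0031). Light harvesting and Rubisco genes were lower in 19 of 20 cases (19 adjusted over the list alone, median -1.55, camera adjusted p = 1.6e-08, adjusted p = 0.52 with an estimated correlation), and the median was -2.42 without replicate 1 of the salt-treated line. LHCB2.1 was at 5.39 ± 2.72 against 14.7 ± 1.16 (-1.47 ± 0.31, edgeR adjusted p = 0.0067). LHCB5 (AT4G10340, chromosome 4, 6408007 to 6409849) was at 87.2 ± 78.1 against 378 ± 19.7 (-2.12 ± 0.48, edgeR adjusted p = 0.0085). The value for LHCB5 was -3.21 without replicate 1 of the salt-treated line, and in a fit of the 6 salt-treated libraries alone it missed the threshold (-2.1, edgeR adjusted p = 0.06).

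Secondary wall cellulose and xylan genes were lower in the line under salt in 10 of 14 cases and higher in 1 (11 and 1 adjusted over the list alone, median -2.51, camera adjusted p = 0.0088, adjusted p = 0.52 with an estimated correlation). CESA4 (AT5G44030, chromosome 5, 17714390 to 17719723), a cellulose synthase of secondary walls, was at 0.63 ± 0.183 against 3.47 ± 2.70 (-2.48 ± 0.55, edgeR adjusted p = 0.0082). CESA7 (-3.63 ± 1.19, edgeR adjusted p = 0.035) and CESA8 (-3.16 ± 0.97, edgeR adjusted p = 0.028) were also lower. IRX7, in contrast, was at 22.6 ± 13.2 against 5.32 ± 0.459 (2.04 ± 0.44, edgeR adjusted p = 0.0074). Replicate 3 of salt-treated wild type had higher levels of 13 of the 14 genes than the mean of its fellows (median difference 1.83), with CESA4 at 6.59 against 1.79 and 2.03. Without it the list median was -1.57 (camera adjusted p = 0.018), CESA4 was at -1.65 (edgeR adjusted p = 0.032), and the calls of CESA7 (-2.20, edgeR adjusted p = 0.18) and CESA8 (-1.98, edgeR adjusted p = 0.14) ended. The calls of CESA7 and CESA8 also ended without replicate 2 or 3 of the salt-treated line (edgeR adjusted p from 0.098 to 0.1), and CESA8 was at -4.97 without replicate 1. In a fit of the 6 salt-treated libraries alone CESA7 (edgeR adjusted p = 0.082) and CESA8 (edgeR adjusted p = 0.083) missed the threshold, as did CESA7 with limma on log2(FPKM + 1) (-1.32, adjusted p = 0.058). The replicate number as a block ended both edgeR calls too (edgeR adjusted p = 0.077 and 0.061). The list call ended without replicate 1 of the salt-treated line (median -2.80, camera adjusted p = 0.084), and with a filter of FPKM 5 the median was -0.06 (camera adjusted p = 0.68). Markers of xylem, which share 4 genes of the secondary wall lists, moved with them, with 3 of 6 lower (6 adjusted over the list alone, median -1.98, camera adjusted p = 0.031, adjusted p = 0.55 with an estimated correlation). Of 5 phloem markers 3 were lower as well (median -0.43, camera adjusted p = 0.27), and 2 were lower without salt (median -0.32, camera adjusted p = 0.21). In a fit of the 6 salt-treated libraries alone the 3 calls under salt, SEOB, SUC2 and PP2A1, ended (edgeR adjusted p from 0.069 to 0.1). The xylem markers had a median of -0.88 without salt (camera adjusted p = 0.15), with 0 of 6 called by edgeR (2 lower at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma).

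The line also had lower primary wall and cuticle genes than wild type under salt. Expansins and xyloglucan hydrolases were lower in 15 of 22 cases and higher in 1 (16 and 1 adjusted over the list alone, median -1.52, or -1.44 with genes at their bound, camera adjusted p = 0.00092, adjusted p = 0.52 with an estimated correlation). XTH4 (AT2G06850, chromosome 2, 2763449 to 2765743) was at 1.87 ± 1.51 against 13.4 ± 5.32 (-2.87 ± 0.51, edgeR adjusted p = 0.0037). XTH24 was higher, at 605 ± 285 against 187 ± 19.5 (1.66 ± 0.32, edgeR adjusted p = 0.0049). Primary wall cellulose genes were lower in 6 of 11 cases (7 adjusted over the list alone, median -0.83, camera adjusted p = 0.0019, adjusted p = 0.52 with an estimated correlation). Cutin and wax genes were lower in 7 of 12 (7 adjusted over the list alone, median -1.21, camera adjusted p = 0.0023, adjusted p = 0.52 with an estimated correlation). PME3 was at 14.1 ± 9.26 against 62.3 ± 3.99 (-2.15 ± 0.35, edgeR adjusted p = 0.0031). Auxin and brassinosteroid growth genes were lower in 10 of 17 cases (13 lower and 2 higher adjusted over the list alone, median -0.95, camera adjusted p = 0.0013, adjusted p = 0.52 with an estimated correlation). They included the sterol reductase gene DIM (-2.13 ± 0.40, edgeR adjusted p = 0.0044). Without replicate 1 of the salt-treated line these medians were -2.84 for expansins and hydrolases, -1.34 for primary wall genes, -2.19 for cuticle genes and -1.77 for growth genes. In a fit of the 6 salt-treated libraries alone the primary wall genes CESA2, AT5G42860 and CTL1 missed the threshold (edgeR adjusted p from 0.076 to 0.092). The cuticle genes GPAT8, CYP96A15 and LACS2 missed it there too (edgeR adjusted p from 0.05 to 0.091).

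In the lignin and sinapate pathways FAH1 was at 25.9 ± 11.6 in the line against 8.86 ± 0.30 in wild type under salt (1.51 ± 0.28, edgeR adjusted p = 0.0038), with 12.5, 31.8 and 33.3 in the 3 libraries of the line. OMT1 was at 183 ± 35.7 against 136 ± 5.19 (0.40 ± 0.14, edgeR adjusted p = 0.052) and CYP84A4 at 2.14 ± 1.76 against 4.31 ± 0.836 (-1.02 ± 0.48, edgeR adjusted p = 0.11). The monolignol list as a whole was not called, with 2 of 19 higher and 3 lower (median 0.07, camera adjusted p = 0.52). 4CL4 (4CL5), a coumarate ligase gene, was higher at 52.3 ± 22.4 against 15.5 ± 3.25 (1.71 ± 0.29, edgeR adjusted p = 0.0032). UGT84A2 was at 27.3 ± 2.66 against 7.62 ± 1.17 (1.82 ± 0.14, edgeR adjusted p = 0.00027). ALDH2C4 (REF1), which makes sinapate and ferulate, was at 82.5 ± 20.2 against 48.6 ± 1.62 (0.73 ± 0.17, edgeR adjusted p = 0.0091), and SNG1 at 61.5 ± 8.90 against 97.4 ± 5.80 (-0.69 ± 0.12, edgeR adjusted p = 0.0036). Of 7 lignin polymerization genes 3 were lower and 1 was higher. The peroxidase gene PER64 had a ratio of 198 in favour of wild type (95% interval 67.4 to 962, edgeR adjusted p = 0.013). That call ended without replicate 3 of salt-treated wild type (-4.87, edgeR adjusted p = 0.056) and without replicates 2 and 3 of the salt-treated line (edgeR adjusted p = 0.055 and 0.053), and in a fit of the 6 salt-treated libraries alone (edgeR adjusted p = 0.053).

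**Figure D3:**
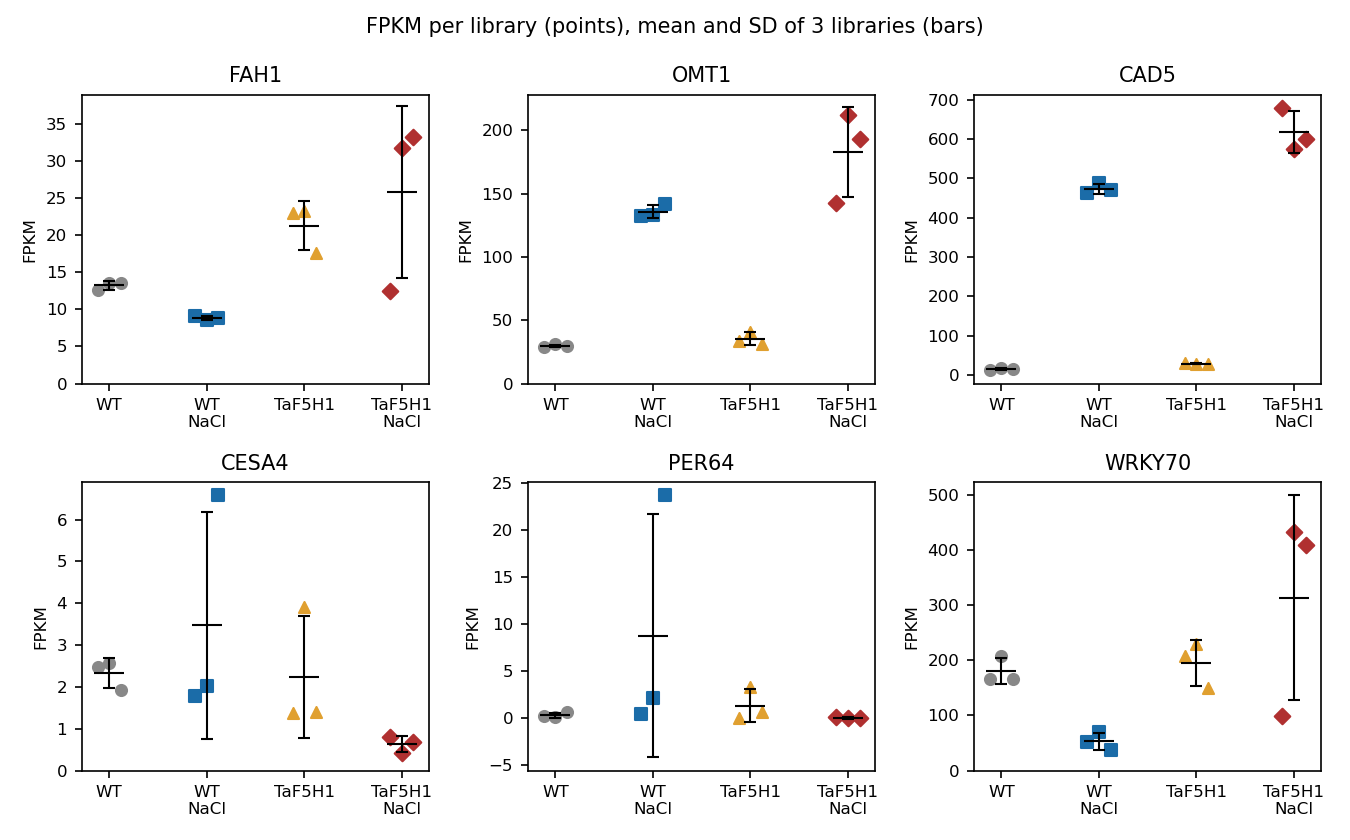
Deposited FPKM of FAH1, OMT1, CAD5, CESA4, PER64 and WRKY70 in each library (vertical axes, FPKM), by group on the horizontal axis; points are libraries, and bars give the mean and SD of 3. FAH1 is highest in replicates 2 and 3 of the salt-treated line (31.8 and 33.3), and CESA4 in replicate 3 of salt-treated wild type (6.59).

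The ABA and dehydration list did not differ as a whole between the genotypes under salt, with 2 of 18 higher (median -0.12, camera adjusted p = 0.68). LTI65 (-0.13, edgeR adjusted p = 0.82), NCED3 (0.50 ± 0.27, edgeR adjusted p = 0.17), NHX1 (0.13, edgeR adjusted p = 0.54), SOS1 (-0.07, edgeR adjusted p = 0.75) and P5CSA (-0.84, edgeR adjusted p = 0.11) did not pass the test. The PP2C phosphatases were higher in 6 of 7 cases (7 adjusted over the list alone, median 0.67, camera adjusted p = 0.00092, adjusted p = 0.52 with an estimated correlation). ABI2 was at 77.3 ± 10.7 against 46.2 ± 4.31 (0.72 ± 0.14, edgeR adjusted p = 0.0053). Stress transcription factors were higher in 9 of 26 cases (10 adjusted over the list alone, median 0.64, camera adjusted p = 0.0016, adjusted p = 0.52 with an estimated correlation). ATHB-12 was at 378 ± 51.3 against 165 ± 10.7 (1.16 ± 0.14, edgeR adjusted p = 0.0014). Jasmonate genes were lower in 9 of 24 cases and higher in 1 (9 and 1 adjusted over the list alone, median -0.53, camera adjusted p = 0.018, adjusted p = 0.55 with an estimated correlation). LOX4 was at 35.0 ± 9.03 against 107 ± 15.0 (-1.64 ± 0.23, edgeR adjusted p = 0.002). Flavonoid genes were higher in 4 of 11 cases (6 adjusted over the list alone, median 0.93, camera adjusted p = 0.022, adjusted p = 0.52 with an estimated correlation). MYB90 was at 88.4 ± 27.6 against 12.5 ± 1.85 (2.78 ± 0.33, edgeR adjusted p = 0.0018). Without replicate 1 of the salt-treated line the calls of the jasmonate list (camera adjusted p = 0.091) and the flavonoid list (camera adjusted p = 0.25) ended and the median of the stress transcription factors was 0.40. The flavonoid call also ended without replicate 2 of salt-treated wild type (camera adjusted p = 0.056) and with a filter of FPKM 5 (camera adjusted p = 0.067).

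The largest differences under salt by the naming rule included PMEI12, at 0 counts in wild type and at least 127-fold higher in the line (edgeR adjusted p = 0.0066), and XTH10 (6.50 ± 0.89, edgeR adjusted p = 0.0019). The response regulator gene ARR7 (AT1G19050, chromosome 1, 6577833 to 6579314) was at 0.767 ± 0.289 against 7.78 ± 2.62 (-3.38 ± 0.32, edgeR adjusted p = 0.00043). In all, edgeR called 5888 genes between the genotypes under salt, 2652 higher in the line (45%) and 3236 lower, with 2833 at least 2-fold. The count was 9185 without replicate 1 of the salt-treated line, 2649 and 2704 without its replicates 2 and 3, and 3586 and 3364 without replicates 1 and 3 of salt-treated wild type. It was 2000 in a fit of these 6 libraries alone (63% higher in the line) and 12284 with sample weights. Across genes the line's difference from wild type correlated between the conditions with r = 0.559 (Spearman 0.427), from comparisons that share no libraries. Both conditions had 567 genes called higher in the line, where independent lists would share 195, and 527 called lower, where they would share 213, and 98 were called in opposite directions. Among genes higher in the line under salt by at least 2-fold, 21 of 43 annotated to systemic acquired resistance were found (2.68 expected, hypergeometric adjusted p = 3.3e-12). Among those lower were 44 of 87 annotated to photosynthesis (8.96 expected, hypergeometric adjusted p = 9.6e-19) and 15 of 35 to secondary wall formation (3.60 expected, adjusted p = 2.5e-05). The photosynthesis and secondary wall lists were not called under salt with an estimated correlation (camera adjusted p = 0.52 for each).

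The interaction asks which genes responded to salt differently in the line. UGT84A2 rose with salt in the line and stayed level in wild type, where it was at 7.74 ± 0.762 and 7.62 ± 1.17 (interaction log2FC 1.92 ± 0.20, edgeR adjusted p = 0.0031). The sinapate ester list was called upwards, with 1 of 5 genes called (2 adjusted over the list alone, median 0.75, camera adjusted p = 0.018, adjusted p = 0.50 with an estimated correlation). The auxin-conjugating enzyme gene GH3.6 (AT5G54510, chromosome 5, 22130964 to 22133688) went from 2.43 ± 0.397 to 33.2 ± 19.3 FPKM in the line and from 4.85 ± 0.977 to 4.77 ± 0.502 in wild type (3.84 ± 0.56, edgeR adjusted p = 0.0088). Genes that were low in the untreated line and lay closer to wild type under salt included EXLA1 (1.89 ± 0.31, edgeR adjusted p = 0.011), PME41 (2.63 ± 0.34, edgeR adjusted p = 0.0065) and FAR1 (3.06 ± 0.51, edgeR adjusted p = 0.012). The same held for the brassinosteroid oxidase gene CYP85A2 (2.02 ± 0.30, edgeR adjusted p = 0.0092) and IAA19 (1.54 ± 0.23, edgeR adjusted p = 0.0089). MYB90 (fitted interaction -7.66 ± 1.21, edgeR adjusted p = 0.014) and PI4KG3 (-5.98 ± 0.99, edgeR adjusted p = 0.012), already high in the untreated line, rose less there. Because MYB90 had 0 counts in untreated wild type its value depends on the prior count and was -0.65 on the log2(FPKM + 1) scale (limma adjusted p = 0.3).

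FAH1 (interaction 0.91 ± 0.38, edgeR adjusted p = 0.15), CYP84A4 (-0.63, edgeR adjusted p = 0.57) and OMT1 (0.25, edgeR adjusted p = 0.45) were not called. Neither were NHX1 (0.35, edgeR adjusted p = 0.33), NCED3 (0.20, edgeR adjusted p = 0.77), P5CSA (0.46, edgeR adjusted p = 0.62) and LTI65 (-0.60, edgeR adjusted p = 0.58). At list level the ABA and dehydration response was smaller in the line (median -0.68, camera adjusted p = 0.00061, adjusted p = 0.69 with an estimated correlation). No member was called singly by edgeR (4 lower adjusted over the list alone, 11 lower at an unadjusted p under 0.05, and 8 by DESeq2). The fall of light harvesting and Rubisco genes was deeper in the line (median -1, camera adjusted p = 0.00061, adjusted p = 0.69 with an estimated correlation). The median was -1.92 without replicate 1 of the salt-treated line, and again edgeR called 0 members (4 at an unadjusted p under 0.05 and 3 by DESeq2, all lower). Jasmonate genes were called lower in 3 of 24 cases (7 adjusted over the list alone, median -0.60, camera adjusted p = 0.013, adjusted p = 0.69 with an estimated correlation). Antioxidant enzyme genes were called lower in 4 of 15 (6 lower and 2 higher adjusted over the list alone, median -0.62, camera adjusted p = 0.015, adjusted p = 0.69 with an estimated correlation). The sinapate call also ended with edgeR's own expression filter (median 0.31, camera adjusted p = 0.058) and with quantile normalization (median 0.70, camera adjusted p = 0.053). The call of the jasmonate list and that of the sinapate list each ended without replicate 1 of the salt-treated line (camera adjusted p = 0.063 for both).

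The secondary wall list was lower in the interaction (median -2.13, camera adjusted p = 0.036, adjusted p = 0.69 with an estimated correlation), with no gene called by edgeR (3 lower adjusted over the list alone, 8 at an unadjusted p under 0.05, and 5 by DESeq2). That call ended without replicate 3 of salt-treated wild type (-1.22, camera adjusted p = 0.09), without replicate 2 of the untreated line (-1.39, camera adjusted p = 0.097) and without replicate 1 of the salt-treated line (-2.65, camera adjusted p = 0.15). The monolignol list had 1 gene higher and 1 lower of 19, a median of 0.05 and a mean of -0.06 (camera adjusted p = 0.77). Its called members were HST (0.91 ± 0.17, edgeR adjusted p = 0.016), which missed the threshold without replicate 1 of salt-treated wild type (edgeR adjusted p = 0.059), and PAL3 (-2.11 ± 0.42, edgeR adjusted p = 0.022). PAL3 missed it without replicate 2 (edgeR adjusted p = 0.05) or 3 (0.054) of untreated wild type, replicate 1 of salt-treated wild type (0.065) or replicate 2 (0.058) or 3 (0.051) of the salt-treated line.

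In all, edgeR called 1001 genes for the interaction, 498 higher and 503 lower in the line, with 728 at least 2-fold, and 4756 had an unadjusted p under 0.05. Scaling by library totals alone shifted the median of all genes to -0.137 and the higher share from 49.8% to 32.8%, and limma on log2(FPKM + 1) gave 31.2%. The count depended on single libraries. It was 262, 267 and 204 without replicates 1, 2 and 3 of untreated wild type, and 129, 221 and 363 without those of salt-treated wild type. It was 344 and 348 without replicates 1 and 2 of the untreated line, and 251 and 222 without replicates 2 and 3 of the salt-treated line, against 6270 without replicate 1 of the salt-treated line. DESeq2 called 2531 genes and limma on log2(FPKM + 1) 1569.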

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

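Of the tests in this part, those of a mislabelled sample, shared control libraries, a single wild-type library, stem or flower tissue and a lower share of xylem cells were chosen after the result was seen. For the mislabelled sample, the stem or flower tissue, the share of xylem cells and the draws of labels for the interaction, the rule that turns the value into a verdict was also changed after the value was known, in each case to the weaker verdict. The count, lists and genes of the next paragraphs are given because the salt response differed between the genotypes by a test of the interaction. The patterns weighed after them were picked by eye from the values of the libraries and lists.

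The interaction was called for 1001 genes. In 100 seeded draws of the genotype labels within each treatment, 2 gave a count as large, the real draw included. The other one called 6080 genes, and it keeps the 4 groups whole while exchanging the genotype labels of the untreated libraries. It therefore points to a structure of the samples, since it tests the sum of the line effects in the 2 conditions. The remaining draws, of which the highest called 717, mix the genotypes and so put the line effects into the spread, which makes a low count nearly certain. Draws that keep the groups whole are too few for a share under 0.05.

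At list level the values were 0.75 for sinapate ester synthesis, -2.13 for secondary wall cellulose and xylan, -0.68 for the ABA and dehydration response, 0.39 for PP2C phosphatases, -0.60 for jasmonate, 0.42 for salicylate and defence, -0.62 for antioxidant enzymes, -0.79 for heat shock and -1 for photosynthesis. None of these calls held with an estimated correlation (adjusted p = 0.50 for sinapate ester synthesis and 0.69 for each of the others). The PP2C, salicylate and heat shock lists, left out of the report here, depend on single libraries. The PP2C call ended without replicates 2 and 3 of untreated wild type (camera adjusted p = 0.062 and 0.051), replicate 3 of salt-treated wild type (0.055), replicate 2 of the untreated line (0.093) and replicate 1 of the salt-treated line (0.15). The salicylate call ended without replicate 2 of untreated wild type (0.059), replicates 1 and 3 of salt-treated wild type (0.07 and 0.089), replicates 2 and 3 of the untreated line (0.059 and 0.16) and replicates 2 and 3 of the salt-treated line (0.13 and 0.091). The heat shock call ended without replicate 2 of the untreated line (0.059). On leaving out single libraries the salicylate median ran from 0.20 to 1.02 and the heat shock median from -1.50 to -0.51. The PP2C median was lowest, 0.22, without replicate 2 of the untreated line. The photosynthesis median was -1.92 without replicate 1 of the salt-treated line, and the secondary wall median -1.22 without replicate 3 of salt-treated wild type. Among other settings, the heat shock call ended with a filter of FPKM 5 (0.23), with limma on log2(FPKM + 1) without and with sample weights (0.064 in each) and after quantile normalization (0.07). The last setting also ended the PP2C (0.07) and salicylate (0.062) calls, and median-of-ratios scaling the salicylate call (0.053).

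Among named genes the largest positive interaction values were those of BHLH100 (10.21), NIMIN-1 (4.38), ORP1A (3.96), GH3.6 (3.84), GRXS7 (3.52) and GRXS3 (3.35). The largest negative values were those of PER64 (-9.38), MYB90 (-7.66), PI4KG3 (-5.98), ETC2 (-5.25), HSP17.4A (-3.68) and PP2A5 (-3.34). Without replicate 1 of the salt-treated line BHLH100 was at 5.71 (edgeR adjusted p = 1) and PP2A5 at -5.58 (edgeR adjusted p = 1.3e-05). BHLH100, MYB90 and ETC2 had a group at 0 counts, and PER64 had nearly none in the salt-treated line, so that their fitted values depend on the prior count. BHLH100 was low in the line without and with salt (0.0967 and 0.117 FPKM), so its value reflects the fall in wild type. With limma on log2(FPKM + 1) PER64 was at -2.82 (adjusted p = 0.12), MYB90 at -0.65 (0.3) and ETC2 at -0.28 (0.45), and with log2(FPKM + 0.1) PER64 was at -5.60 (0.072).

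In the phenylpropanoid and wall lists the flagged genes were HST (0.91), PAL3 (-2.11), UGT84A2 (1.92), MYB75 (-2.44), MYB4 (-1.61), EXLA1 (1.89), XTH27 (0.75), PME41 (2.63), FAR1 (3.06) and CER1 (3.08). In ion transport they were HA2 (1.19), NHX4 (1.91) and AKT1 (-1.33), and in the hormone lists LOX4 (-1.65), OPR3 (-1.26), AOC1 (-1.51), ERF2 (-1.58), SARD1 (2.49), WRKY70 (2.49), IAA19 (1.54) and CYP85A2 (2.02). In the stress and clock lists they were RBOHD (-1.01), FSD3 (-1.90), FSD1 (-1.52), HSP17.7 (-3.73) and PRR3 (-1.33). With limma on log2(FPKM + 1) the calls of HSP17.7 (-0.75, adjusted p = 0.085), CER1 (1.75, 0.075) and WRKY70 (2.21, 0.054) ended, as they did for HSP17.7 (-0.33, 0.41) and AKT1 (-0.79, 0.053) after quantile normalization. Other filters ended the calls of XTH27 (0.73 with no filter, edgeR adjusted p = 0.06) and FSD1 (-1.52 with edgeR's own filter, edgeR adjusted p = 0.051). With the replicate number as a block the calls of BHLH100 (edgeR adjusted p = 0.055), PER64 (0.056), PP2A5 (0.059), MYB4 (0.06) and XTH27 (0.059) ended. Those of CER1 (0.056), NHX4 (0.053), AKT1 (0.065), WRKY70 (0.05) and FSD1 (0.056) ended as well. Of the 38 named genes called in the interaction, 26 lost the call without some single library. GH3.6, GRXS7, GRXS3, MYB90, PI4KG3, UGT84A2, EXLA1, PME41, FAR1, IAA19, CYP85A2 and PRR3 kept it without each.

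Replicate 1 of the salt-treated line lay between salt-treated wild type and its fellows. RNA mixed with salt-treated wild type is argued against, since the shares from lower and higher genes differed by 0.45 (medians 0.558 and 0.109), and lower depth is too, since a library thinned to that depth differed from its fellow with an SD of only 0.381, against 0.91 and 0.881 observed. A wrong genotype label cannot be told apart from a true difference by 86 marker genes, of which 86% lay on the line's side of 3 wild-type libraries (chance 25%, fellows 89.5% and 91.9%), with a median shift of 1.12 (quartiles 0.58 to 1.49), since replicate 2 of salt-treated wild type also lay on that side of the other two for 64% (chance 33.3%), with a shift of 0.37 (-0.02 to 0.74), unlike replicates 1 and 3 (16.3% and 19.8%, shifts -0.02 and -0.31). On genes chosen without the library placed, its quartiles between wild type (0) and its fellows (1) overlapped those of that replicate (0.14 to 0.46 and -0.05 to 0.19) but not those of replicate 1 (0.13 to 0.44 and -0.07 to 0.12) or 3 (0.12 to 0.42 and -0.16 to 0.09), and its PP2C level (3.62) was that of its fellows (3.60 and 3.51) and above salt-treated wild type (2.89 to 2.91). RNA mixed with the untreated line is likewise open, because its shares differed by 0.194 with overlapping quartiles (medians 0.646 and 0.841), as is a weaker or later salt response of those seedlings, which was not tested.

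Untreated seedlings of the line differed from untreated wild type on balance, but not throughout, in the direction of the salt response. With the wild-type response 791 genes were shared up, 667 shared down and 249 opposite, with the line's own response 619, 497 and 565, and the cutin and wax list went the other way (median -0.89, against 0.81 and 1.12 with salt). Shared control libraries are argued against as the whole source, because with the line's own salt response, where sharing acts downwards, the covariance was 0.275 against -0.0434 in 20 simulations without effects (r = 0.256 against -0.498). With the wild-type response, where sharing acts upwards, the covariance was 0.427 against 0.0438, although r (0.45) lay under the simulated 0.501. A single untreated library is argued against, since the lowest r on leaving each out was 0.189, without replicate 3 of the untreated line. An effect of the genotype stays as a hypothesis, found and tested on the same data, and other differences between the 2 sets of seedlings, such as growing conditions, were not tested.

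Secondary wall genes were lower in the line than in wild type under salt. A single wild-type library is argued against as the whole source, since without replicate 3 the median was still -1.57. Stem or flower tissue in that library cannot be told apart from a change in leaves, since the markers had a median of -0.10 but 3 of 4 have a high leaf level that would hide a small share, and the remaining one, SEP3, was 1.7 higher. A lower share of xylem cells cannot be told apart from lower expression per cell, since the estimates for XCP1 and XCP2 were -1.48 and -1.44, at least the 2-fold difference that this explanation needs, but neither passed the test (edgeR adjusted p = 0.097 and 0.054). Without salt they were already at -1.76 and -1.47 (edgeR adjusted p = 0.11 and 0.086), and under salt phloem markers were lower in 3 of 5 cases as well (median -0.43), while an effect of the genotype on the wall stays open and was not tested apart from these.

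For the comparisons of 3 against 3 libraries, only 10 splits exist, too few for a share under 0.05. In each, 1 split (the real one) gave a count as large, with real values of 9160 for salt in wild type, 11047 for salt in the line, 2371 for the line without salt and 5888 for the line under salt. The highest count of any other split was 0 in each. Every other split mixes the groups compared and so puts their difference into the spread, which makes a low count nearly certain.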

How the results depend on the processing

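DESeq2, edgeR's own expression filter and library totals were chosen after the data were seen, as was the place of limma on log2(FPKM + 1), the test planned in advance, among the alternatives. No called result changed direction under any of 26 settings. Without leaving out libraries, 175 gene values lost the call and 89 gained it, as did 72 and 19 list values; on leaving out single libraries 465 and 40 gene values and 25 and 18 list values did so. In simulated counts at the depth of these libraries the recovery of 2-fold changes was lowest for the interaction, at 3.17%. Other depths, group sizes or shares of changed genes were not simulated. Where a value below moved, the cause was not tested unless fewer genes or libraries entered the fit.

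The correlation of the salt responses was 0.626 without a filter, 0.877 with a mean FPKM of at least 5, 0.831 with edgeR's filter and 0.814 with sample weights, against 0.857. With a fit of only the groups compared, the line differed in 3992 genes without salt and 2000 under salt, against 2371 and 5888. Sample weights gave 6065, 12284 and, for the interaction, 8329. The interaction count was 1569 with limma on log2(FPKM + 1), 1604 after quantile normalization and 2531 with DESeq2, against 1001. A minimum of 2-fold left 5084 genes for salt in wild type, 6462 for salt in the line, and 1180 and 2833 for the line without and under salt.

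The secondary wall list was at -0.06 under salt and -0.15 in the interaction with a mean FPKM of at least 5, where fewer members were tested. In the interaction it was at -1.01 with limma on log2(FPKM + 1), -1.82 with log2(FPKM + 0.1), -0.86 after quantile normalization and -0.73 with sample weights, past no threshold. With an estimated correlation the medians stayed and the calls ended, for the ABA and dehydration response at 6.03, 4.13 and -0.68 (salt in wild type, salt in the line, interaction) and for the secondary wall list at -2.51 and -2.13 (line under salt, interaction).

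With the replicate number as a block the counts were 8933, 10850, 2098, 5616 and 644 in the order of the comparisons. Of 18 pairs of libraries with the same number, 4 had deviations that correlated above 0.1 (range -0.26 to 0.24), so the numbers were not taken to pair the samples.

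On leaving out each library, counts ranged from 7727 to 10812 for salt in wild type and from 9926 to 12126 for salt in the line. They ranged from 1160 to 5121 for the line without salt, from 2649 to 9185 under salt, and from 129 to 6270 for the interaction. Each highest count came without replicate 1 of the salt-treated line. The correlation of the salt responses ranged from 0.807 to 0.87. The ABA and dehydration list ranged from 5.95 to 6.20 in wild type, 3.72 to 4.51 in the line and -0.88 to -0.59 in the interaction, and the secondary wall list from -0.90 to 0.13 without salt, -2.85 to -1.57 under salt and -2.65 to -1.22 in the interaction. The monolignol list ranged from 0.02 to 0.11 without salt, 0.05 to 0.12 under salt and -0.08 to 0.08 in the interaction.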

Other observations

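The iron lists in this part were chosen after BHLH100 had been seen, so their tests are not planned ones. Genes that store iron rose with salt in both genotypes. The ferritin gene FER1 rose by 2.67 ± 0.25 in wild type (edgeR adjusted p = 4.3e-06) and by 3.26 ± 0.25 in the line (edgeR adjusted p = 9e-07). FER3 rose by 1.80 ± 0.13 in wild type (edgeR adjusted p = 6.4e-07) and by 2.82 ± 0.13 in the line (edgeR adjusted p = 3.6e-08), and the interaction was called (1.01 ± 0.18, edgeR adjusted p = 0.015). All 3 storage genes tested rose in each genotype (medians 1.80 and 2.82), while FER2 lay below the expression filter and was not tested.

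Genes of the iron deficiency response other than BHLH100 fell with salt in wild type in 4 of 5 tested cases (median -1.17), while in the line 2 rose and 2 fell (median 0.08). Without salt 2 of the 5 were already lower in the line and 0 higher (median -0.69). BHLH38, BHLH39 and BHLH101 lay below the expression filter and were not tested. The transporter gene OPT3, which carries iron in the phloem, fell by 2.31 ± 0.29 in wild type (edgeR adjusted p = 4.6e-05) and by 2.51 ± 0.29 in the line (edgeR adjusted p = 2.1e-05). The reductase gene FRO3 fell by 1.17 ± 0.28 in wild type (edgeR adjusted p = 0.004) and rose by 1.03 ± 0.28 in the line (edgeR adjusted p = 0.0062), with an interaction of 2.21 ± 0.39 (edgeR adjusted p = 0.015). In the interaction FRO3 was the only one of these 5 genes called (median 0.92).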
